A study of Mus musculus with 31 samples.

How the data were processed

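The values analysed were gene counts as deposited by the authors, in 3 tables of 7, 8 and 16 libraries with 45706 gene identifiers each. According to the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.4 and counted per gene with featureCounts (no version given) on the mouse build mm10, from RNA of sorted cells amplified with a SMARTer Ultra protocol that does not mark strand. The aligner is not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies, are therefore uncertain, since reads from such genes cannot be told apart. Gene symbols came from GENCODE M21, which gave a symbol to 45143 identifiers. The remaining 563 kept their identifier and held 0.0574 to 0.0908% of each library's counts. Gene positions are those of the count tables.

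Libraries were assigned to 8 groups from their titles. Table columns carry neither the day nor the 5-FU treatment. The table of 7 columns went to day 7, the only set with 3 β-glucan and 4 PBS libraries, the table of 16 columns, which includes MPP, to day 28, and the table of 8 columns to 5-FU. Column names of the last 2 tables give only P or G, read as PBS and β-glucan. 1 library titled as MPP of PBS mice carried an HSC tag, and the title was followed. All 31 libraries and all columns of per-library values were used. Counts per library ran from 19331663 to 39485556 (median 29751400), with the 10 highest genes holding 12.1 to 32.9% of them. A comparison of the counts of all 45 replicate pairs found no duplicated library (chi-square per gene 6.75 to 50.3).

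Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM, and tested with edgeR's quasi-likelihood fit of the groups compared, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences between β-glucan effects were tested as a contrast of 4 groups in 1 fit. Levels are CPM on TMM-scaled totals. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. The comparisons, tests, 33 gene lists and alternatives were fixed before the data were examined. The lists held 859 members, of which 855 matched a symbol in the tables. Sgol1, Ahsp, Emr1 and Igj did not. Lists were tested by camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists. Counts of members adjusted over the list alone come from the same gene p-values.

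Genes named in the text followed a rule fixed beforehand: up to 8 genes of the largest change in each direction among called, separated genes of mean log2 CPM of at least 2 with a standard name; the 8 next smallest p; up to 4 members of the smallest p for each list described, which were those that camera called; and 11 genes of prior interest (Ly6a, Kit, Slamf1, Cd48, Flt3, Cd34, Procr, Mki67, Il1r1, Csf2rb and Clec7a). For differences between effects, up to 6 called genes were named. Other genes in the text are members of the fixed lists, picked as examples after the results were seen. Values of some single genes are not reported here.

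The procedure was tested on simulated data, negative binomial counts with the means, library sizes and dispersions of the real libraries and 200 changed genes. The changed genes were drawn only from those of mean CPM of at least 5. The shares recovered therefore do not cover tested genes of lower level. Of the genes changed 2-fold, edgeR recovered 89.6% in HSC at day 7, 98.5% in HSC at day 28, 98.5% in MPP, 95.5% after 5-FU and 98.5% between cell types, and at 1.5-fold 44.8, 56.7, 85.1, 76.1 and 82.1%. For the differences of day 28 against day 7, MPP against HSC and 5-FU against day 28 it recovered 76.1, 92.5 and 85.1% at 2-fold and 19.4, 37.3 and 34.3% at 1.5-fold. In the same 8 simulations, in that order, 18 of 174, 5 of 174, 19 of 208, 17 of 198, 8 of 195, 10 of 140, 9 of 162 and 7 of 152 calls of edgeR were false, a larger share than the threshold of 0.05 in all but HSC at day 28, MPP against HSC in PBS mice and 5-FU against day 28. With DESeq2 38 of 210, 20 of 203, 27 of 221, 43 of 232, 38 of 230, 32 of 178, 25 of 194 and 28 of 191 were false, a larger share than 0.05 in all 8. With nothing changed edgeR called 0 to 4 genes, and DESeq2 was not run on such counts. A 1.5-fold change of the neutrophil list was found by camera in all 8 comparisons, with no other list called. The simulated genes were drawn independently, whereas members of real lists can move together (estimated correlation 0.75 for the neutrophil list at day 7). The simulation therefore cannot show how often camera with the preset correlation calls real lists falsely.

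Alternatives fixed beforehand were DESeq2 size factors, no filter, a stricter filter (CPM of at least 5), the DESeq2 1.42.0 Wald test, limma voom with quality weights, all 8 groups in 1 fit, the replicate number as a block, a fold change over 1.5 by glmTreat, each library left out in turn, and lists of 200 genes for the day 7 genes. Added after seeing the data were a GC offset per library (lowess with span 0.3, for 99.6% of tested genes), 1 surrogate factor from sva 3.50.0, removal of the haemoglobin genes and 4 sets of 2 or 4 libraries left out together. GC content, and the share of a gene's 50-base stretches found in another gene, were computed from the longest transcript of each gene in GENCODE M21. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.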

Results

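Gene counts were compared between RNA-seq libraries from bone marrow cells of C57BL/6 mice (10 weeks old) injected into the peritoneum with PBS or with 1 mg of β-glucan, a fungal cell wall polysaccharide recognised by dectin-1. Long-term hematopoietic stem cells (HSC) were sorted 7 days after injection (4 PBS and 3 β-glucan libraries) and 28 days after injection (4 and 4). Multipotent progenitors (MPP) were sorted at day 28 (4 and 4). A further set of HSC (4 and 4) came from mice that received 150 mg/kg of 5-fluorouracil (5-FU) 7 days after PBS or β-glucan and were sampled 14 days after the 5-FU. The 31 libraries formed 8 groups and held 19331663 to 39485556 counts each (median 29751400), with 21717 to 23713 genes detected. The count tables did not print the day or the 5-FU treatment: the table with MPP columns was taken as day 28, since MPP were sorted only then, and the initials P and G in column names were taken as PBS and β-glucan. The labels do not say whether replicates were separate mice, so p-values measure the spread between these samples. Below, a gene was called when its adjusted p was under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and values after gene names are log2 fold changes ± standard errors.

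Transcripts of mature blood cells made up a large part of every library. The 4 haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt held 5.78 ± 0.686% of counts (mean ± SD) in HSC of PBS mice at day 7 and 2.03 ± 0.307% in HSC of β-glucan mice. Their share was 17.6 ± 0.491% and 15.7 ± 0.784% in HSC at day 28, 15.7 ± 1.15% and 13.1 ± 1.62% in MPP, and 13.8 ± 1.6% and 11 ± 1.37% in HSC after 5-FU. The 17 mature neutrophil markers (such as Camp, Ltf and Lcn2, which encode granule proteins) held 5.98 ± 0.349% and 9.91 ± 1.83% in HSC at day 7 and 17.1 ± 2.13% and 17 ± 1.05% after 5-FU. The 32 LT-HSC markers held 0.285 ± 0.0191% and 0.285 ± 0.0443% in HSC at day 7, and 0.104 ± 0.0194% and 0.0854 ± 0.00322% in HSC at day 28. Shares in different tables were not tested against each other, and genes with near-identical copies, ribosomal protein genes aside, stood lower in the day 7 table. The groups, the tests, the gene lists and the rule for naming genes were fixed before the data were examined.

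**Figure D1:**
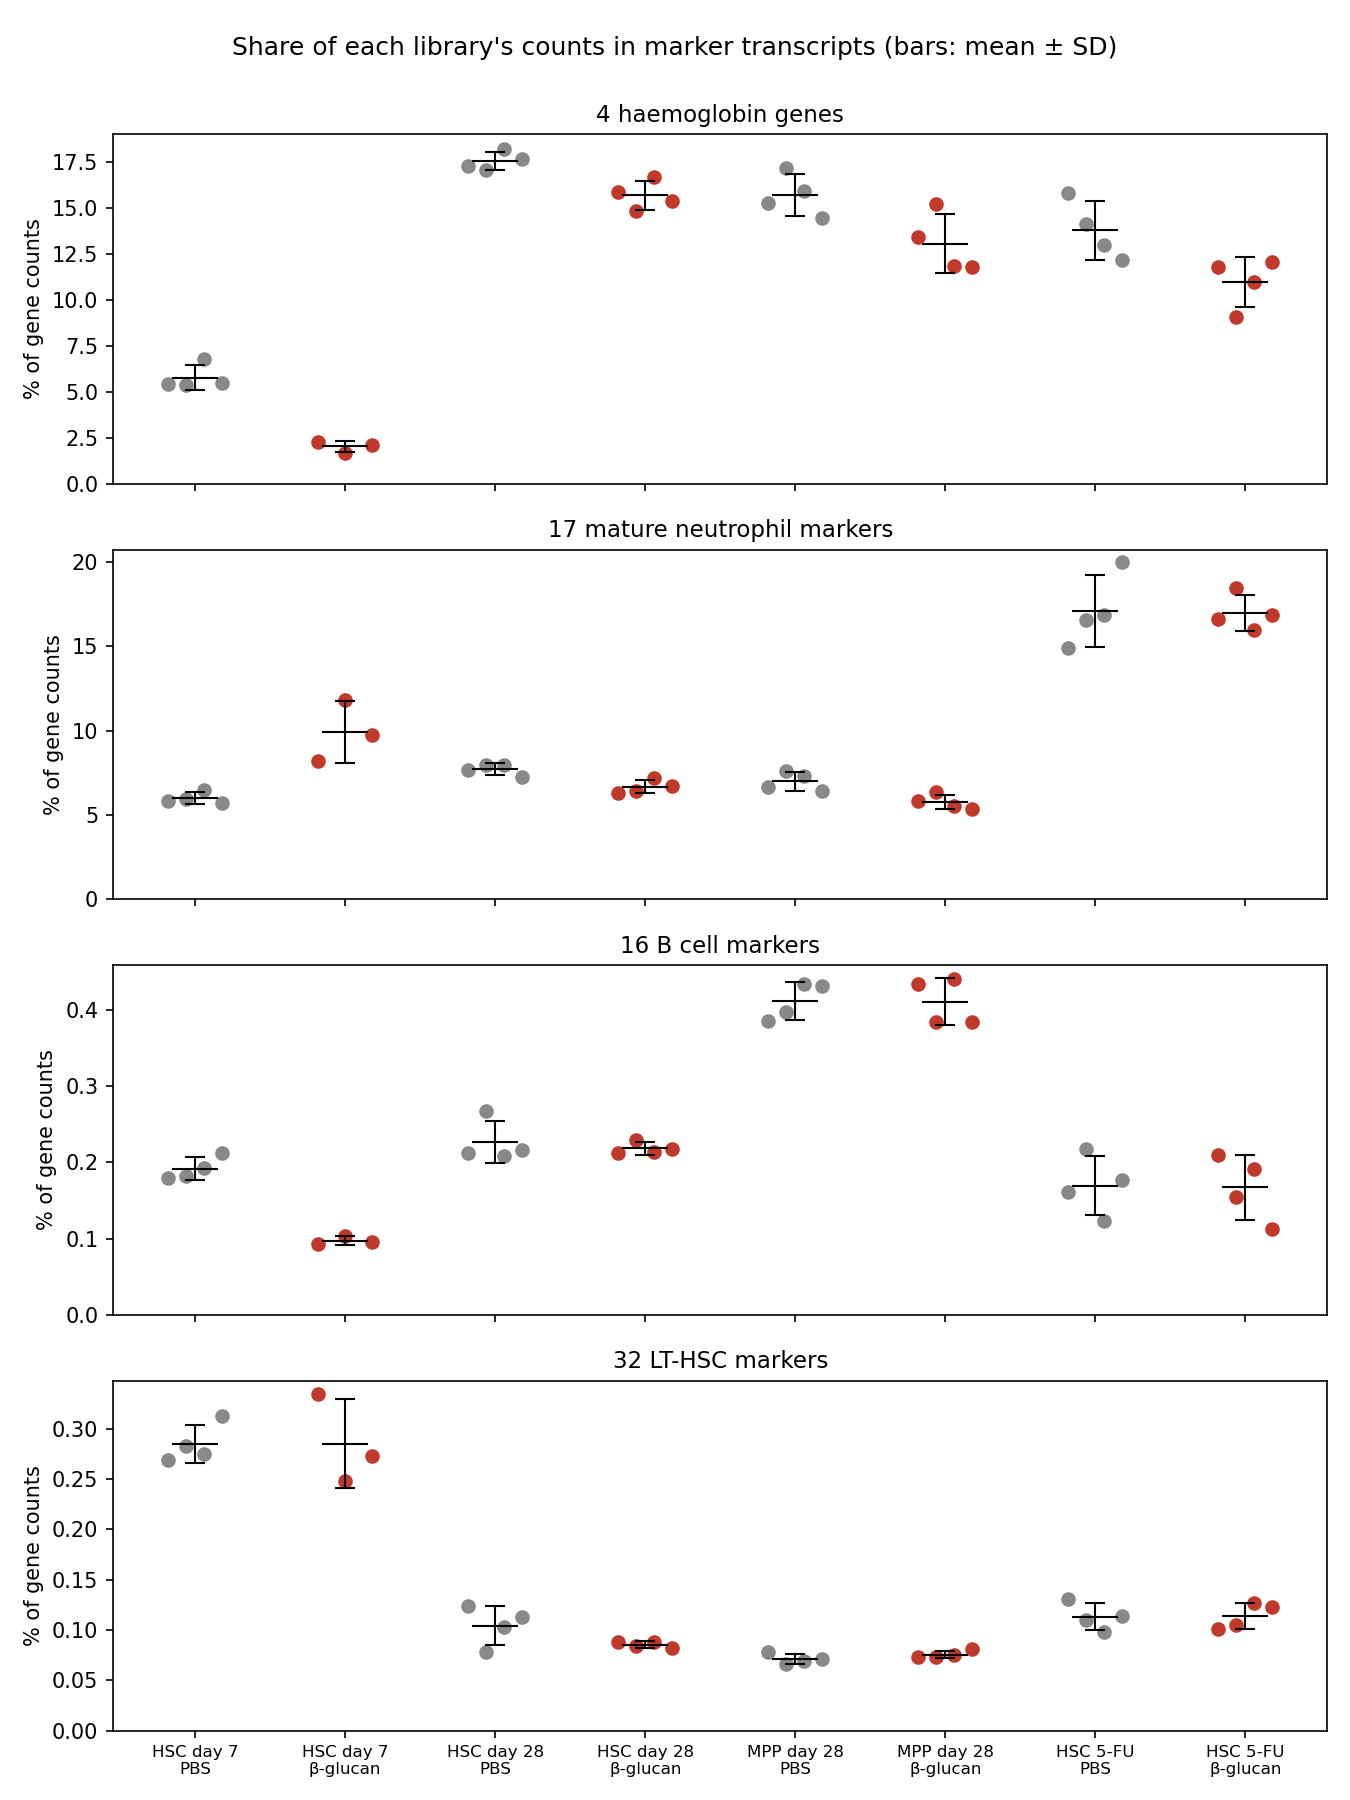
Share of gene counts in haemoglobin genes, neutrophil markers, B cell markers and LT-HSC markers in each of the 31 libraries, with the mean and SD per group. At day 7 haemoglobin genes held 5.78% of counts in PBS and 2.03% in β-glucan HSC.

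At day 7, red cell and B cell transcripts were lower, and granulocyte transcripts higher, in HSC of β-glucan mice (n = 3) than in HSC of PBS mice (n = 4). The α-globin gene Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298 in mm10) stood at 3173 CPM against 9375 CPM in PBS mice (-1.56 ± 0.10), and Alas2 (ENSMUSG00000025270, chromosome X, 150547375 to 150570638), the first enzyme of heme synthesis in red cells, at 943 against 2432 CPM (-1.37 ± 0.09). Ms4a1, which encodes the B cell antigen CD20, stood at 20.7 against 66.8 CPM (-1.69 ± 0.12). Prtn3 (ENSMUSG00000057729, chromosome 10, 79874476 to 79883174), a primary granule protease of granulocyte precursors, rose from 448 to 939 CPM (1.07 ± 0.12). In these 4 genes the adjusted p was at most 0.000494 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

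Of 16403 genes tested, 1102 were called, 465 higher and 637 lower, and 311 of them changed over 2-fold (67 higher, 244 lower). Of the 21 erythroid genes tested, 17 fell over all genes (21 adjusted over the list alone), with a median of -1.08, among them the β-globin gene Hbb-bs (-1.43 ± 0.12) and the erythroid factor Klf1 (-0.82 ± 0.21). For the erythroid list, camera gave adjusted p = 1.38e-20, and adjusted p = 0.148 with an estimated correlation. Outside that list, Epb41, a red cell membrane skeleton gene (-1.05 ± 0.07), and Bpgm, an enzyme of red cell glycolysis (-1.37 ± 0.10), fell too. Of 16 B cell markers, 13 fell (15 adjusted over the list alone; median -1.40), among them the B cell receptor chains Cd79a (-1.51 ± 0.12) and Ighd (-2.08 ± 0.17). For the B cell list, camera gave adjusted p = 3.16e-17, and adjusted p = 0.127 with an estimated correlation. Lymphoid priming genes went mostly the same way, with 7 lower and 1 higher of 24 (10 and 3 adjusted over the list alone): the B lineage factor Ebf1 (-1.53 ± 0.20) and the adaptor Blnk (-1.04 ± 0.16) fell, and Wfdc17 (1.12 ± 0.18) rose. That list had a camera adjusted p of 0.00145, and adjusted p = 0.291 with an estimated correlation.

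Granulocyte and monocyte genes were higher. Of 26 granulocyte-monocyte priming genes, 17 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.71), including Ms4a3 (1.12 ± 0.13), Ly6c2 (1.00 ± 0.11) and the protease Ctsg (1.09 ± 0.14). Of 17 mature neutrophil markers, 11 rose (13 adjusted over the list alone; median 0.74), including the ficolin Fcnb (1.10 ± 0.11), the antimicrobial peptide gene Camp (0.92 ± 0.13) and Lcn2, an iron-siderophore binding protein (0.81 ± 0.13). The camera adjusted p was 1.44e-14 for the priming list and 2.4e-10 for the neutrophil list, and adjusted p = 0.291 with an estimated correlation for each. Of 30 genes of IL-1, TLR and dectin-1 signalling, 7 rose (8 adjusted over the list alone), among them Card9 (1.28 ± 0.17), the adaptor downstream of dectin-1, Myd88 (0.59 ± 0.08), the adaptor of IL-1 and Toll-like receptors, and Tlr4 (0.56 ± 0.10), the lipopolysaccharide receptor. For the dectin-1 signalling list, camera gave adjusted p = 0.00052, and adjusted p = 0.291 with an estimated correlation. The dectin-1 gene Clec7a itself was not called (0.16 ± 0.16). Of 20 GM-CSF, G-CSF and M-CSF signalling genes, 4 rose and 1 fell (8 and 1 adjusted over the list alone): Csf2rb (ENSMUSG00000071713, chromosome 15, 78325990 to 78351000), the shared β chain of the GM-CSF, IL-3 and IL-5 receptors (0.54 ± 0.11), and the feedback inhibitors Socs3 (1.09 ± 0.22) and Socs2 (0.75 ± 0.17) rose, and the survival gene Bcl2l1 fell (-0.98 ± 0.07). Its camera adjusted p was 0.00481, with adjusted p = 0.139 with an estimated correlation. Neutrophil markers held 9.91% of counts in these β-glucan libraries, against 5.98% in PBS libraries. Whether these signalling genes, or the metabolic, interferon and cell cycle genes below, changed within stem cells or with the cell mix was not tested.

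Metabolic and interferon genes also moved at day 7. Of 24 cholesterol synthesis genes, 8 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.31), including Msmo1 (0.61 ± 0.08), Cyp51 (0.52 ± 0.11) and Sc5d (0.49 ± 0.09). This was the only list of the day 7 comparison still called with an estimated correlation (camera adjusted p = 7.13e-09; adjusted p = 0.0354 with an estimated correlation). Of 22 glycolysis genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone), among them Pfkp (0.39 ± 0.07) and Gpi1 (0.50 ± 0.10) higher and the lactate transporter Slc16a1 lower (-0.72 ± 0.14). For the glycolysis list, camera gave adjusted p = 0.000131, and adjusted p = 0.127 with an estimated correlation. Of 29 interferon gamma response genes, 6 rose (16 adjusted over the list alone), including the transcription factor Irf1 (0.60 ± 0.09), the immunoproteasome subunit Psmb9 (0.45 ± 0.08) and the MHC class I gene H2-D1 (0.38 ± 0.09). For the interferon gamma list, camera gave adjusted p = 7.11e-08, and adjusted p = 0.291 with an estimated correlation. Type I interferon genes were mixed, with 6 higher, such as the nucleic acid sensor Zbp1 (0.97 ± 0.18), and 1 lower, Rsad2 (-1.01 ± 0.09), of 33 (8 and 2 adjusted over the list alone). That list was up by camera (adjusted p = 0.00571; adjusted p = 0.63 with an estimated correlation).

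The proliferation marker Mki67 fell (-0.70 ± 0.10), as did Cd34 (-0.40 ± 0.08) and Kit, the stem cell factor receptor (-0.40 ± 0.10), and Ly6a, which encodes Sca-1, rose (0.45 ± 0.11). Of 39 DNA replication genes, 3 fell (6 adjusted over the list alone), Pole (-0.53 ± 0.09), Rrm2 (-0.41 ± 0.08) and Pola1 (-0.39 ± 0.08). For the DNA replication list, camera gave adjusted p = 4.24e-05, and adjusted p = 0.291 with an estimated correlation. Of 33 mitosis genes, 4 fell (4 adjusted over the list alone), among them Cenpe (-0.37 ± 0.08) and Cenpf (-0.58 ± 0.12), and camera did not call the list (adjusted p = 0.346). The HSC markers Slamf1 (0.57 ± 0.22) and Procr (0.09 ± 0.10), the IL-1 receptor Il1r1 (-0.13 ± 0.15), Flt3 (-0.41 ± 0.20) and Cd48 (0.19 ± 0.13) were not called, and 2 of the LT-HSC markers rose and 0 fell.

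Markers of other cell types moved with the groups: dendritic cell markers (5 lower of 15, median -0.51) had a camera adjusted p of 0.000131, and adjusted p = 0.127 with an estimated correlation. Monocyte and macrophage markers (5 higher of 19, median 0.23) had a camera adjusted p of 0.00306, and adjusted p = 0.291 with an estimated correlation. T and NK cell markers were lower (2 of 20 called, 2 adjusted over the list alone, median -0.28), among them Cd2 (-1.17 ± 0.15), with a camera adjusted p of 0.00277, and adjusted p = 0.291 with an estimated correlation. Megakaryocyte priming genes were higher (2 of 24 called, 4 adjusted over the list alone, 21 with a positive value, median 0.61), among them the adhesion gene Selp (1.19 ± 0.16), with a camera adjusted p of 0.000341, and adjusted p = 0.291 with an estimated correlation. Camera also called the unfolded protein response (median 0.20), oxidative phosphorylation (0.08) and ribosomal protein lists (0.05) up, and the DNA repair (-0.17) and MHC class II lists (-0.19) down, each with adjusted p of at least 0.291 with an estimated correlation. Every day 7 library of 1 arm lay above every library of the other for 18.9% of genes, against 5.71% expected by chance. Leaving out β-glucan library 3 brought the count of called genes to 500, and DESeq2 called 1711. Hba-a1, Hba-a2 and Hbb-bs share 67.5%, 86.9% and 65.8% of their sequence with other genes, so the level of each copy alone is uncertain.

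**Figure D2:**
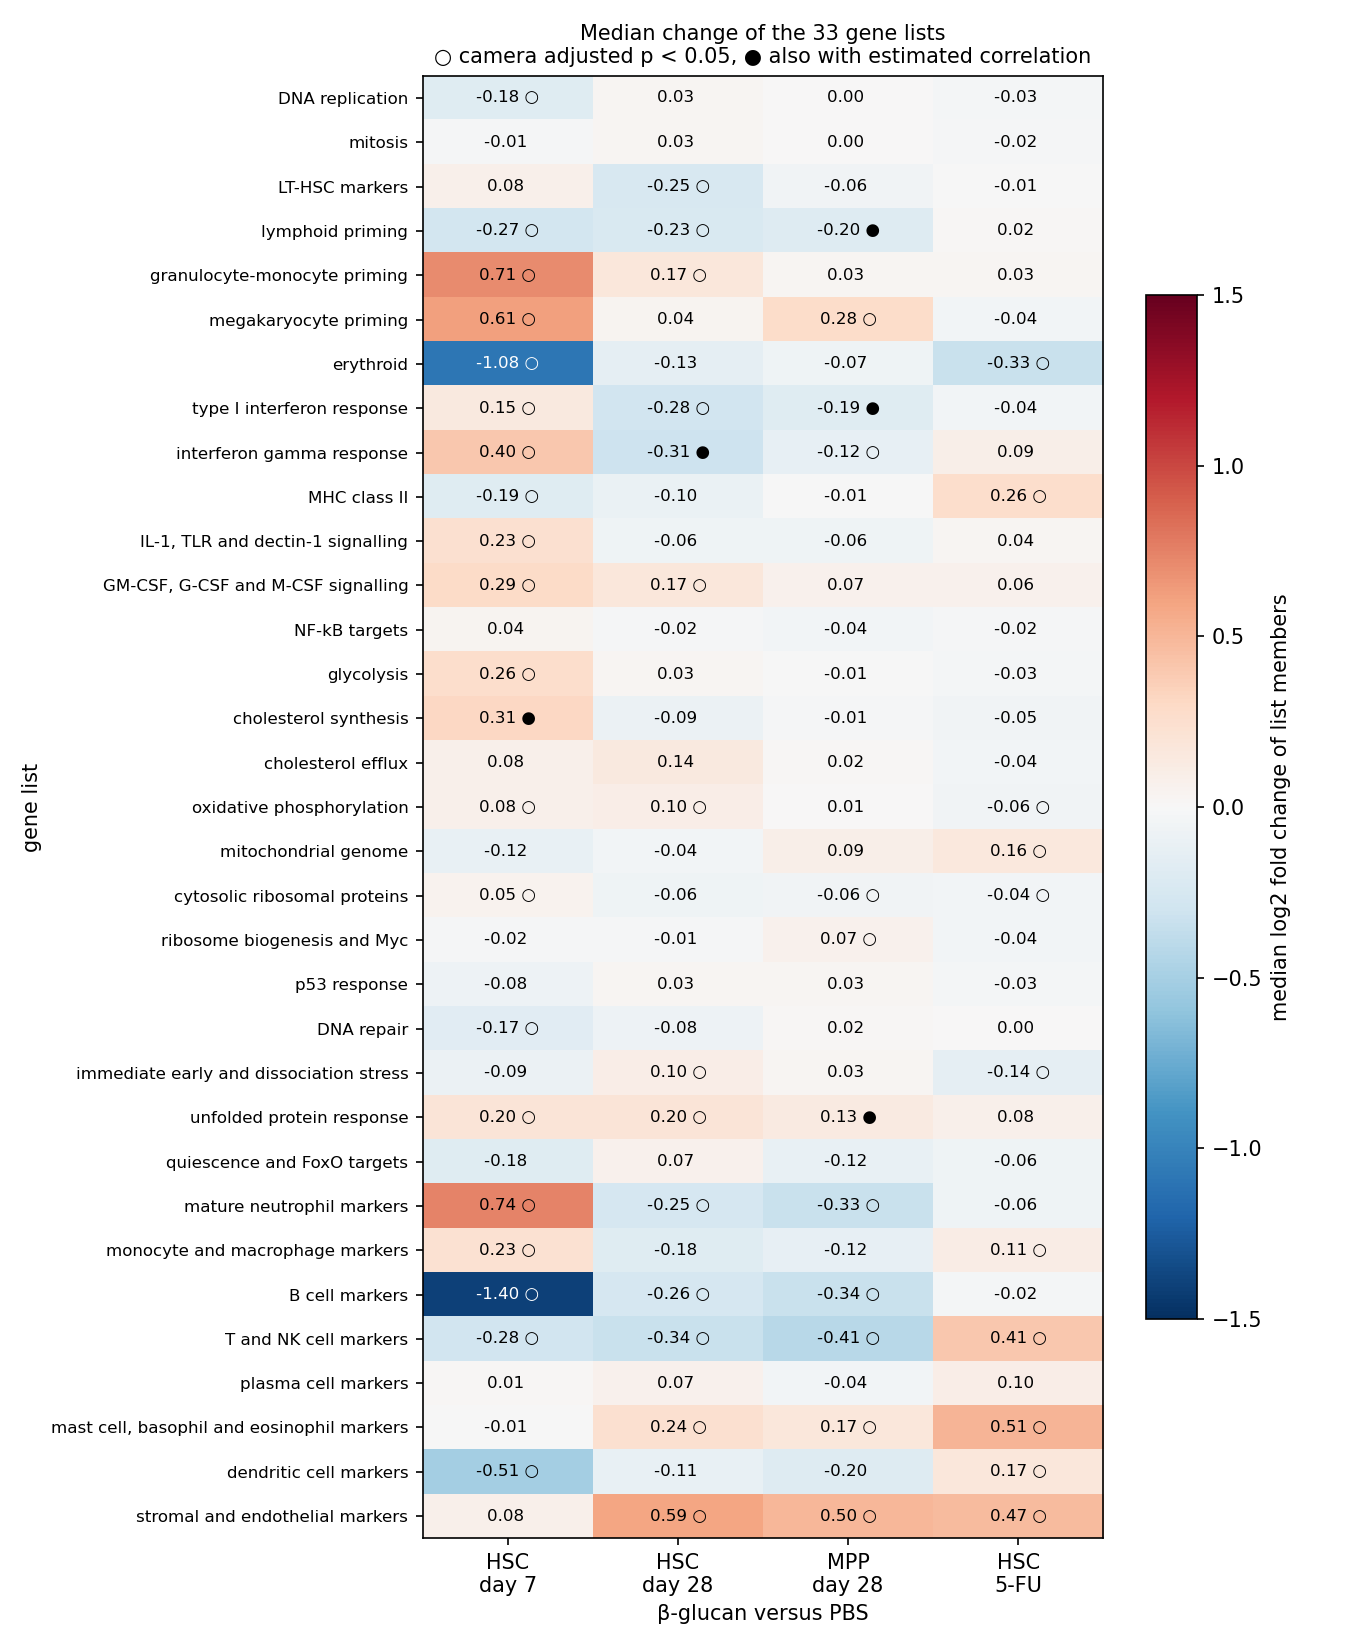
Median log2 fold change of the 33 gene lists in the 4 β-glucan comparisons. Erythroid genes had a median of -1.08 at day 7 and -0.33 after 5-FU.

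At day 28 the HSC of β-glucan mice (n = 4) differed from those of PBS mice (n = 4) in few single genes. Sdf2l1 (ENSMUSG00000022769, chromosome 16, 17130138 to 17132383), an endoplasmic reticulum chaperone partner, stood at 143 against 67.7 CPM (1.08 ± 0.14), and Lipg, endothelial lipase, at 15.3 against 5.88 CPM (1.38 ± 0.19). The metalloprotease gene Adamts5 (1.57 ± 0.23), Tspan7 (1.51 ± 0.21) and the antibody light chain segments Igkv4-91 (4.04 ± 0.31) and Igkv17-127 (3.37 ± 0.39) were the other genes called. All 6 of 16025 genes were higher, with adjusted p from 0.000519 to 0.049 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2729 genes had p under 0.05. DESeq2 called 589 genes and limma voom with quality weights 598.

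Several gene lists shifted as a whole in HSC at day 28, though apart from Sdf2l1 none of their members was called over all genes. Interferon gamma response genes were lower: 0 of 29 fell over all genes and 15 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 8.16e-09; adjusted p = 0.0404 with an estimated correlation, the only list of this comparison to keep its call). The guanylate binding protein Gbp2 was at -0.59 ± 0.09 and the immunity-related GTPase Iigp1 at -0.61 ± 0.12. Type I interferon genes were likewise lower (18 of 33 adjusted over the list alone), with Oasl2 at -0.46 ± 0.08 and Ifi27l2a at -0.36 ± 0.07. For the type I interferon list, camera gave adjusted p = 1.05e-09, and adjusted p = 0.13 with an estimated correlation. The unfolded protein response list was higher, with 1 of 20 called over all genes and 6 adjusted over the list alone, and with Manf at 0.53 ± 0.08 and Creld2 at 1.00 ± 0.19. For the unfolded protein response list, camera gave adjusted p = 0.000132, and adjusted p = 0.13 with an estimated correlation. Granulocyte-monocyte priming genes were higher, with 6 up and 1 down of 26 adjusted over the list alone (Prtn3 0.58 ± 0.09, Ms4a3 0.45 ± 0.09), while mature neutrophil markers were lower, with 3 of 17 down adjusted over the list alone (Camp -0.44 ± 0.08). The camera adjusted p was 0.0101 for the priming list, with adjusted p = 0.38 with an estimated correlation, and 7.05e-05 for the neutrophil list, with adjusted p = 0.38 with an estimated correlation.

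LT-HSC markers as a list were lower at day 28 (median -0.25, 0 of 31 called, 0 adjusted over the list alone; camera adjusted p = 0.00169, adjusted p = 0.619 with an estimated correlation), with Meis1, a stem cell transcription factor, at -0.47 ± 0.16 and Txnip at -0.63 ± 0.17. Markers of other cells moved too: T and NK cell markers were lower (median -0.34; camera adjusted p = 1.96e-09, adjusted p = 0.13 with an estimated correlation) and so were B cell markers (median -0.26; camera adjusted p = 3.4e-06, adjusted p = 0.251 with an estimated correlation). Stromal and endothelial markers were higher, with 0 of 20 called over all genes and 4 higher and 1 lower adjusted over the list alone (median 0.59; Kitl 0.72 ± 0.17; camera adjusted p = 0.000247, adjusted p = 0.38 with an estimated correlation). Mast cell, basophil and eosinophil markers were higher too (median 0.24; camera adjusted p = 0.0351, adjusted p = 0.38 with an estimated correlation), as were immediate early and dissociation stress genes (median 0.10; Fos 0.95 ± 0.17; camera adjusted p = 0.0059, adjusted p = 0.365 with an estimated correlation). Camera also called the lymphoid priming list down (median -0.23) and the GM-CSF signalling (0.17) and oxidative phosphorylation lists (0.10) up, each with adjusted p of at least 0.13 with an estimated correlation. Kit was at -0.48 ± 0.10, Cd34 at -0.34 ± 0.09, Mki67 at 0.35 ± 0.12, Clec7a at -0.43 ± 0.13 and Csf2rb at 0.18 ± 0.08, none of them called. The count of called genes changed with every single library left out: it was 1 without PBS library 3 or 4 (1 of the 6 genes kept), 2 without PBS library 1 (1 kept), 3 without β-glucan library 1, 2 or 4 (3, 2 and 3 kept), 28 without β-glucan library 3 (5 kept) and 51 without PBS library 2 (6 kept). Without PBS library 2 and β-glucan library 3, a choice made after seeing the data, it was 669 (376 higher). Separation of all libraries of 1 arm from the other held for 9.11% of genes, against 2.86% expected by chance.

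In MPP at day 28, early B lineage genes were lower and endoplasmic reticulum chaperone genes higher in β-glucan mice (n = 4) than in PBS mice (n = 4). Vpreb1 (ENSMUSG00000059305, chromosome 16, 16868402 to 16870843), a surrogate light chain of the pre-B cell receptor, stood at 17.9 against 34.2 CPM (-0.93 ± 0.08), and Igll1, its partner, at 44.5 against 86.8 CPM (-0.96 ± 0.08). Hspa5, the main chaperone of the endoplasmic reticulum, stood at 1471 against 1126 CPM (0.38 ± 0.05) and Manf, which is induced by stress there, rose (0.43 ± 0.04). The immediate early gene Fos rose (0.91 ± 0.07). In these 5 genes the adjusted p was at most 0.00385 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

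Of 15828 genes tested in MPP, 733 were called, 431 higher and 302 lower, and 106 changed over 2-fold (97 higher, 9 lower). The balance of directions depended on the fit, with 204 higher and 24 lower with all 8 groups in 1 fit, and 106 higher and 151 lower without PBS library 1. Of 24 lymphoid priming genes, 7 fell and 1 rose (11 and 1 adjusted over the list alone). Among them Ebf1 (-0.51 ± 0.06), the IL-7 receptor gene Il7r (-0.50 ± 0.07) and the recombinase genes Rag1 (-0.79 ± 0.12) and Rag2 (-0.71 ± 0.10) fell. The lymphoid priming list kept its call (camera adjusted p = 3.44e-06; adjusted p = 0.0356 with an estimated correlation). Of 16 B cell markers, 10 fell (10 adjusted over the list alone), including Vpreb3 (-0.69 ± 0.07), Cd79a (-0.47 ± 0.05) and Vpreb1. For the B cell list, camera gave adjusted p = 1.32e-10, and adjusted p = 0.099 with an estimated correlation. Of 20 unfolded protein response genes, 7 rose (13 adjusted over the list alone), among them Sdf2l1 (1.42 ± 0.20) and Creld2 (1.10 ± 0.16), with a camera adjusted p of 7.41e-07; the call held, adjusted p = 0.0356 with an estimated correlation. Of 33 type I interferon genes, 10 fell (22 adjusted over the list alone), including Ifit3 (-0.54 ± 0.09), Ifi27l2a (-0.53 ± 0.09) and Isg15 (-0.31 ± 0.07), and this list also kept its call (camera adjusted p = 3.3e-12; adjusted p = 0.0356 with an estimated correlation).

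Markers of mature cells moved with treatment in MPP. Of 20 T and NK cell markers, 10 fell (15 adjusted over the list alone), including the granzyme Gzma (-0.70 ± 0.11) and the NK receptor Klrb1c (-0.54 ± 0.09), and of 17 mature neutrophil markers 9 fell (14 adjusted over the list alone), including Ltf (-0.41 ± 0.08) and Mmp8 (-0.33 ± 0.07). The camera adjusted p was 1.09e-13 for T and NK cells, with adjusted p = 0.099 with an estimated correlation, and 3.06e-09 for neutrophils, with adjusted p = 0.363 with an estimated correlation. Of 23 megakaryocyte priming genes, 4 rose (5 higher and 1 lower adjusted over the list alone), including the platelet chemokines Ppbp (2.48 ± 0.49) and Pf4 (0.57 ± 0.13) and the integrin Itga2b (0.38 ± 0.08). For the megakaryocyte list, camera gave adjusted p = 0.00307, and adjusted p = 0.516 with an estimated correlation. Stromal and endothelial markers were higher, with 2 of 18 up, the niche factor Cxcl12 (0.46 ± 0.07) and Lepr (0.75 ± 0.15), and 1 down, Alpl (-0.79 ± 0.12; 2 and 1 adjusted over the list alone; median 0.50; camera adjusted p = 0.00613, adjusted p = 0.199 with an estimated correlation). Of 15 mast cell, basophil and eosinophil markers, 2 rose (5 adjusted over the list alone; median 0.17), the basophil proteases Prss34 (0.27 ± 0.06) and Mcpt8 (0.21 ± 0.05; camera adjusted p = 0.00329, adjusted p = 0.238 with an estimated correlation). Of 26 granulocyte-monocyte priming genes, 6 rose and 2 fell (7 and 7 adjusted over the list alone), and camera did not call the list (median 0.03; adjusted p = 0.363).

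Ribosomal protein genes in MPP as a list were down by camera (adjusted p = 0.0471; adjusted p = 0.89 with an estimated correlation; median -0.06), yet the 2 called members, Rpl13 (0.45 ± 0.08) and Rps2 (1.33 ± 0.27), were higher. The list was up without β-glucan libraries 3 and 4, a choice made after seeing the data (camera adjusted p = 0.0232), and up but not called without library 3 alone (0.783). Camera also called the interferon gamma list down (median -0.12) and the ribosome biogenesis list up (0.07), each with adjusted p of at least 0.199 with an estimated correlation. Flt3 rose (0.85 ± 0.22) and Clec7a fell (-0.27 ± 0.07), whereas Kit (-0.10 ± 0.09), Cd34 (0.11 ± 0.09), Mki67 (0.00 ± 0.08), Slamf1 (0.21 ± 0.21) and Csf2rb (0.01 ± 0.04) were not called. Without the same 2 libraries, 189 genes were called (122 higher), and adding 1 surrogate factor left 12 calls and put Flt3 at -0.09.

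**Figure D3:**
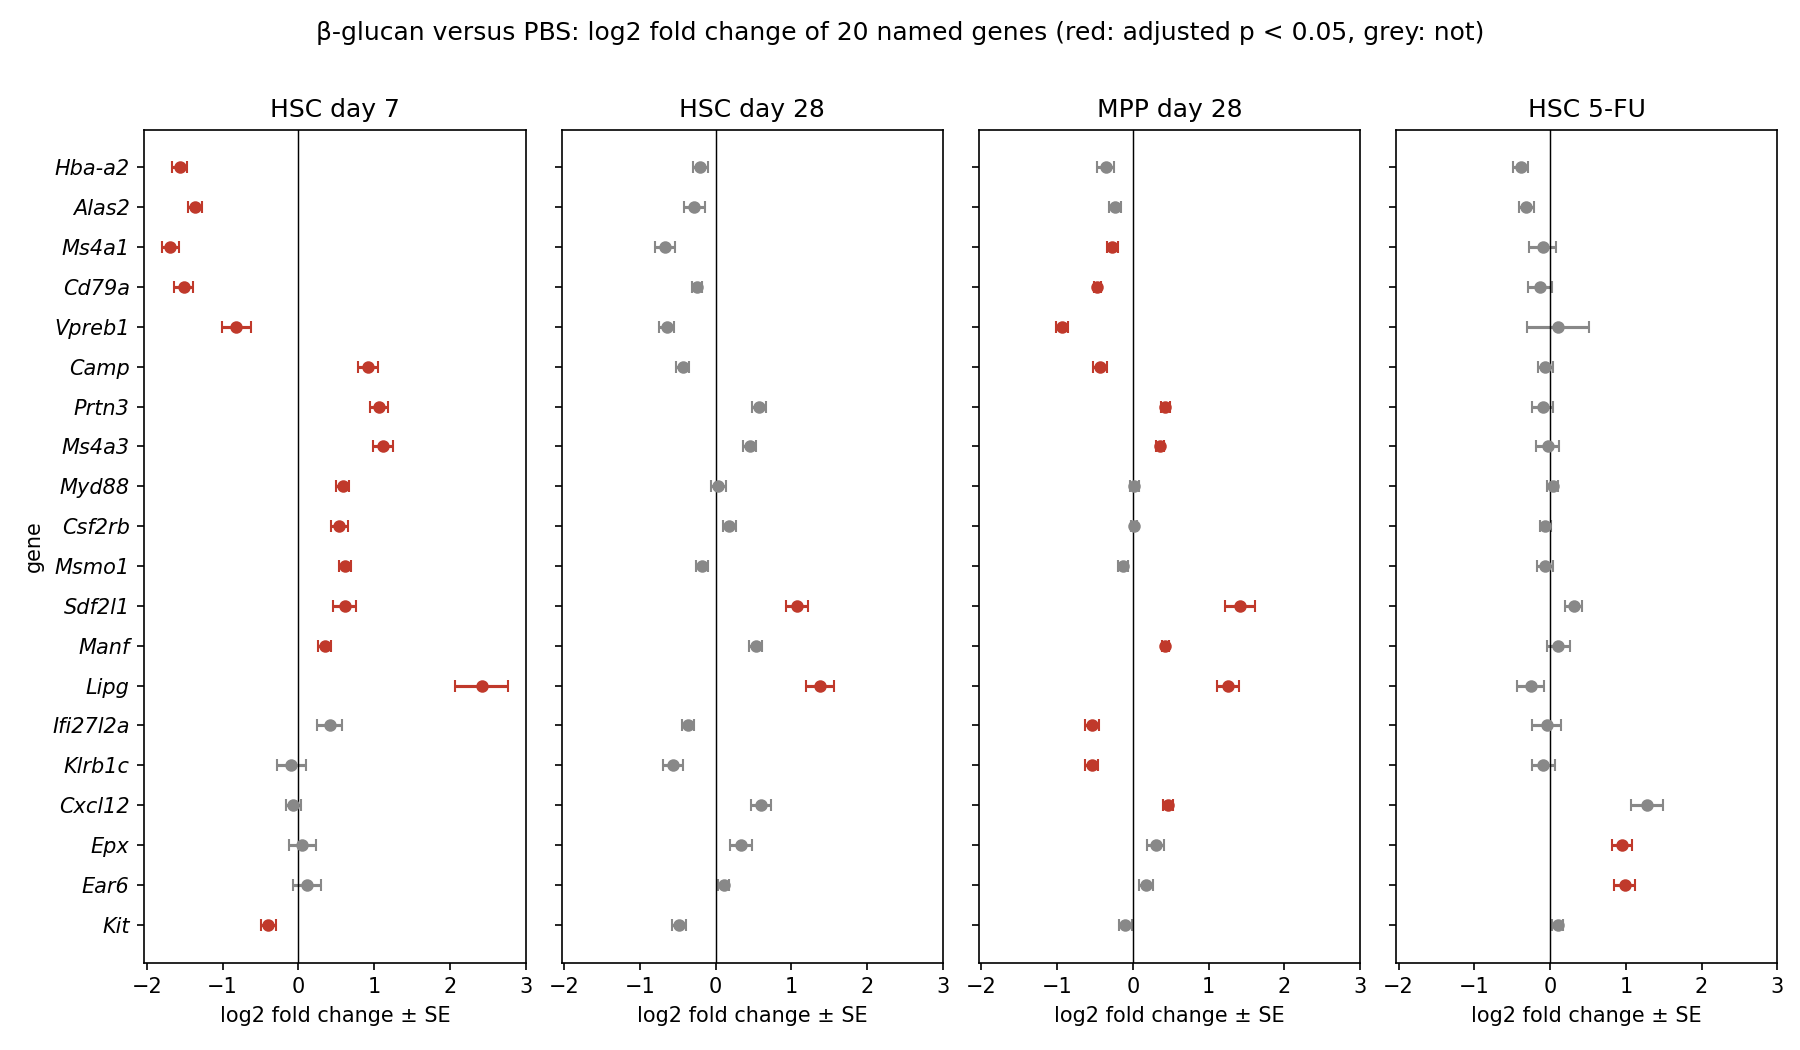
Log2 fold change ± standard error of 20 named genes in the 4 β-glucan comparisons. Sdf2l1 stood at 0.61 ± 0.15 in HSC at day 7, 1.08 ± 0.14 in HSC at day 28, 1.42 ± 0.20 in MPP and 0.31 ± 0.11 after 5-FU.

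After 5-FU, eosinophil genes were higher in HSC of β-glucan mice (n = 4) than of PBS mice (n = 4). Epx (ENSMUSG00000052234, chromosome 11, 87864000 to 87875536), eosinophil peroxidase, stood at 476 against 247 CPM (0.95 ± 0.13), and the eosinophil ribonuclease genes Ear1 (0.90 ± 0.10) and Ear6 (0.98 ± 0.13) were higher as well. The extracellular matrix gene Bgn, biglycan (1.03 ± 0.12), the BMP antagonist Chrdl1 (1.37 ± 0.18) and the glucocorticoid-induced Tsc22d3 (0.56 ± 0.08) rose, and the antibody heavy chain segment Ighv1-49 fell (-4.21 ± 0.31). These were the 7 genes called of 15705, with adjusted p from 0.000283 to 0.0482 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Whether RNA of eosinophil and other cell markers came from other cells in the sort was not tested, here or at day 28.

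Of 14 mast cell, basophil and eosinophil markers, 2 rose over all genes and 9 adjusted over the list alone, with the granule major basic protein Prg2 at 0.88 ± 0.14 and Prg3 at 0.97 ± 0.16. For the mast cell and eosinophil list, camera gave adjusted p = 4.35e-09, and adjusted p = 0.204 with an estimated correlation. Of 19 stromal and endothelial markers, 0 were called over all genes and 8 were higher adjusted over the list alone, with the niche factors Cxcl12 at 1.27 ± 0.21 and Kitl at 1.13 ± 0.22 and the leptin receptor gene Lepr at 1.13 ± 0.22. For the stromal list, camera gave adjusted p = 4.42e-10, and adjusted p = 0.334 with an estimated correlation. Of 21 erythroid genes, 0 were called over all genes and 14 were lower adjusted over the list alone, with Slc4a1, the red cell anion exchanger, at -0.44 ± 0.10. For the erythroid list, camera gave adjusted p = 4.42e-10, and adjusted p = 0.438 with an estimated correlation. T and NK cell markers were higher (6 of 20 adjusted over the list alone), with Trac at 0.83 ± 0.13 and Il2rb at 0.90 ± 0.15. For the T and NK cell list, camera gave adjusted p = 2.14e-07, and adjusted p = 0.0646 with an estimated correlation. MHC class II genes were higher as a list, 4 of 10 adjusted over the list alone (H2-Eb1 0.50 ± 0.09; camera adjusted p = 2.6e-05, adjusted p = 0.329 with an estimated correlation).

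Genes of the mitochondrial genome were higher as a list after 5-FU, with 0 of 13 called over all genes and 7 adjusted over the list alone (median 0.16; mt-Nd4 0.27 ± 0.06; camera adjusted p = 1.59e-07, adjusted p = 0.438 with an estimated correlation). They held 1.69 ± 0.0615% of counts in β-glucan and 1.45 ± 0.128% in PBS libraries. Camera also called monocyte and macrophage (median 0.11) and dendritic cell markers (0.17) up, and immediate early (-0.14), oxidative phosphorylation (-0.06) and ribosomal protein genes (-0.04) down, each with adjusted p of at least 0.329 with an estimated correlation. Kit (0.10 ± 0.07), Cd34 (0.08 ± 0.09), Slamf1 (-0.30 ± 0.12), Mki67 (0.05 ± 0.18) and Clec7a (0.16 ± 0.15) were not called. The count of 7 was 61 without PBS library 3 and 2 without β-glucan library 1, DESeq2 called 147 genes, and all libraries of 1 arm lay apart for 4.61% of genes, against 2.86% expected by chance.

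Between cell types, MPP of PBS mice at day 28 (n = 4) held more lymphoid transcripts and fewer megakaryocyte and stem cell transcripts than HSC of PBS mice (n = 4). Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059523), which adds nucleotides during antigen receptor rearrangement, stood at 317 against 63.1 CPM (2.33 ± 0.11). Vwf (ENSMUSG00000001930, chromosome 6, 125546774 to 125686679), von Willebrand factor, stood at 5.11 against 29.4 CPM (-2.52 ± 0.16), and Slamf1, an HSC surface marker, at 1.16 against 5.87 CPM (-2.33 ± 0.24). Flt3 (1.03 ± 0.11), Cd34 (1.26 ± 0.10) and Cd48 (0.73 ± 0.07), which mark progenitors, were higher in MPP. In these 6 genes the adjusted p was at most 0.000173 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

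Of 16122 genes tested, 3493 were called between MPP and HSC, 1544 higher and 1949 lower, and 537 differed over 2-fold (180 higher, 357 lower). Of 23 megakaryocyte priming genes, 22 were lower (22 adjusted over the list alone; median -2.01), including Pf4 (-2.55 ± 0.20) and the platelet receptor Gp1ba (-2.34 ± 0.18). For the megakaryocyte list, camera gave adjusted p = 7.66e-16, and adjusted p = 0.183 with an estimated correlation. Of 30 LT-HSC markers, 21 were lower and 0 higher (24 and 1 adjusted over the list alone), including the angiopoietin receptor Tek (-1.93 ± 0.19). For the LT-HSC marker list, camera gave adjusted p = 2.32e-14, and adjusted p = 0.21 with an estimated correlation. Of 24 lymphoid priming genes, 14 were higher and 1 lower (14 and 2 adjusted over the list alone), including Blnk (0.83 ± 0.07) and the chemokine receptor Ccr9 (0.92 ± 0.08). For the lymphoid priming list, camera gave adjusted p = 7.09e-07, and adjusted p = 0.0667 with an estimated correlation. Of 76 ribosomal protein genes, 35 were higher and 1 lower (59 and 1 adjusted over the list alone). For the ribosomal protein list, camera gave adjusted p = 4.98e-14, and adjusted p = 0.42 with an estimated correlation. Of 29 genes of ribosome biogenesis and Myc, 20 were higher and 1 lower (21 and 2 adjusted over the list alone), such as the nucleolar genes Ncl (0.57 ± 0.08) and Npm1 (0.47 ± 0.06). For the ribosome biogenesis list, camera gave adjusted p = 3.7e-09, and adjusted p = 0.21 with an estimated correlation. The cell cycle inhibitors Cdkn1c (-1.76 ± 0.28) and Cdkn1b (-0.68 ± 0.10) were lower and Mki67 higher (0.53 ± 0.07). Camera called neither cell cycle list, however. Of 39 DNA replication genes, 3 were higher and 5 lower (median 0.004, camera adjusted p = 0.694). Of 33 mitosis genes, 3 were higher and 2 lower (median 0.012, camera adjusted p = 0.327).

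Other cell markers differed between MPP and HSC too: 10 of 14 dendritic cell markers (11 adjusted over the list alone; camera adjusted p = 3.44e-08, adjusted p = 0.0574 with an estimated correlation) and 8 of 10 MHC class II genes, such as H2-Eb1 (0.70 ± 0.06) and H2-Aa (0.55 ± 0.07), were higher in MPP (8 adjusted over the list alone; camera adjusted p = 7.09e-07, adjusted p = 0.0574 with an estimated correlation). Of 21 erythroid genes, 15 were lower (17 adjusted over the list alone), among them the erythroid factor Klf1 (-1.99 ± 0.15). For the erythroid list, camera gave adjusted p = 4.12e-08, and adjusted p = 0.379 with an estimated correlation. Camera also called B cell markers higher (7 of 16 called, 9 higher and 3 lower adjusted over the list alone; median 0.26; adjusted p = 0.00154, adjusted p = 0.475 with an estimated correlation) and plasma cell markers higher (6 of 11 called, 6 adjusted over the list alone; median 0.98; adjusted p = 0.000508, adjusted p = 0.183 with an estimated correlation). It called mature neutrophil markers lower (6 of 17 called, 8 adjusted over the list alone; median -0.26; adjusted p = 0.000508, adjusted p = 0.539 with an estimated correlation). Mast cell, basophil and eosinophil markers were lower by camera as well (8 of 15 lower and 2 higher, 10 and 2 adjusted over the list alone; median -0.49; adjusted p = 0.0472, adjusted p = 0.42 with an estimated correlation). Further lists called by camera were oxidative phosphorylation (median 0.10) and DNA repair (0.08), higher, and GM-CSF signalling (-0.21) and quiescence (-0.32), lower, each with adjusted p of at least 0.21 with an estimated correlation.

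Kit (-0.13 ± 0.10), Procr (-0.62 ± 0.21) and Csf2rb (-0.04 ± 0.07) were not called. 1 MPP library of PBS mice carried the tag of HSC beside an MPP title, and its title was followed: Dntt stood at 371 CPM in it, against 263 to 349 CPM in the other MPP libraries and 58.8 to 66.3 CPM in HSC. Without that library 2004 genes were called.

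The β-glucan effect in HSC at day 28 differed from that at day 7 in 866 of 17977 genes (403 with a larger and 463 with a smaller value at day 28). Without β-glucan library 2 of day 7 the count was 445, and DESeq2 called 1432 and limma voom 1611. The 2 days came as separate tables, so day cannot be told apart from other differences between the sets. In PBS HSC of day 7 and day 28, haemoglobin genes held 5.78 and 17.6% of counts and LT-HSC markers 0.285 and 0.104%. Taking each effect against its own PBS group need not remove such differences. The red cell spectrin gene Sptb (1.94 ± 0.17), Ighd (1.98 ± 0.18), Hba-a2 (1.34 ± 0.14) and Epb41 (1.04 ± 0.11) had a larger value at day 28, with adjusted p of at most 7.16e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By list, 16 erythroid genes and 11 B cell markers had a larger value at day 28, and 11 neutrophil markers, 12 interferon gamma genes and 8 cholesterol synthesis genes a smaller one. B cell markers (camera adjusted p = 2.58e-15; adjusted p = 0.0454 with an estimated correlation) and cholesterol synthesis (camera adjusted p = 2.07e-08; adjusted p = 0.0219 with an estimated correlation) kept their call. The erythroid list (camera adjusted p = 1.17e-22) had adjusted p = 0.0716 with an estimated correlation, the neutrophil list (camera adjusted p = 1.34e-14) had adjusted p = 0.112 with an estimated correlation, and the interferon gamma list (camera adjusted p = 2.69e-13) had adjusted p = 0.108 with an estimated correlation.

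At day 28 the effect in MPP differed from that in HSC in 1 gene, the light chain segment Igkv4-91 (-6.64 ± 0.84), with adjusted p = 0.0047 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1033 of 16691 genes had p under 0.05. Interferon gamma genes had a larger value in MPP as a list (median 0.17, camera adjusted p = 1.99e-05, adjusted p = 0.0602 with an estimated correlation). LT-HSC markers (median 0.25) and megakaryocyte priming genes (0.295) were also called by camera, with larger values in MPP. B cell markers (-0.175), GM-CSF signalling (-0.17) and granulocyte-monocyte priming genes (-0.088) were called with smaller values. Each of these had adjusted p of at least 0.791 with an estimated correlation. The 5-FU and day 28 sets also came as separate tables, so 5-FU cannot be told apart from other differences between them. The effect in HSC after 5-FU differed from that at day 28 in 18 of 16985 genes (9 larger, 9 smaller). Among them Il2rb, the IL-2 receptor β chain (1.44 ± 0.18), Trac, the T cell receptor α constant region (0.96 ± 0.16), and the lipoxygenase Alox15 (1.36 ± 0.20) had a larger value after 5-FU. The T and NK cell list differed in the same direction, with 2 of 20 members called and 12 adjusted over the list alone (median 0.68; camera adjusted p = 4.55e-15; adjusted p = 0.000686 with an estimated correlation). Camera also called other lists for 5-FU against day 28. Among them, interferon gamma (median 0.474, camera adjusted p = 4.79e-09) and MHC class II genes (0.265, 3.66e-06) had larger values after 5-FU, and erythroid genes smaller ones (-0.207, 0.000115). With an estimated correlation these 3 lists had adjusted p of 0.172, 0.17 and 0.497. Without β-glucan libraries 3 and 4 of day 28, a choice made after seeing the data, 2 genes were called for 5-FU against day 28. For MPP against HSC, edgeR called 0 genes when both cell types lost them (1017 with p under 0.05), where DESeq2 called 2 and limma voom 1 with all libraries.

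The 465 genes higher and 637 genes lower at day 7 were followed in the other comparisons. In HSC at day 28 the higher genes had a camera adjusted p of 0.671 and the lower genes of 0.153. In MPP at day 28, 28 of the 465 higher genes rose and 45 fell (camera adjusted p = 0.0167, down; adjusted p = 0.927 with an estimated correlation), and 8 of the 637 lower genes rose and 59 fell (camera adjusted p = 1.63e-07, down; adjusted p = 0.63 with an estimated correlation). After 5-FU the lower genes were down as a list (camera adjusted p = 5.98e-08; adjusted p = 0.63 with an estimated correlation), with none called, and the higher genes had a camera adjusted p of 0.671. Among genes called at day 7 and in MPP, Prtn3 rose in both (1.07 ± 0.12 and 0.43 ± 0.06), Camp rose at day 7 (0.92 ± 0.13) and fell in MPP (-0.43 ± 0.09), and Cd79a fell in both (-1.51 ± 0.12 and -0.47 ± 0.05).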

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

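The counts of splits and the tests of explanations in this part were chosen after the results they weigh had been seen, whereas the differences between effects had been planned. Splits of the same libraries into other groups were counted first. In HSC at day 7, 1 of 35 splits (the real one, 1102 genes) called as many genes, and the highest other called 1. The same count was 1 of 35 in MPP (733 against 1), 1 of 35 after 5-FU (7 against 3) and 1 of 35 between MPP and HSC (3493 against 2). In HSC at day 28, 2 of 35 splits called at least 6 genes, and the highest other called 12, so the splits do not exclude chance there. The split with 12 calls exchanged only PBS library 2 and β-glucan library 3, so treatment itself can give its calls. The next highest called 3. Among 100 splits of the differences between effects, 1 called as many genes for day 28 against day 7 (866, highest other 439), 20 for MPP against HSC (1, highest other 205) and 2 for 5-FU against day 28 (18, highest other 23). Splits for MPP against HSC regrouped the cell types independently of each other and so parted HSC and MPP libraries of the same number, which leaves this count undecided if those share a source. The split with 205 calls reversed the arms in HSC and exchanged only library 1 of each arm in MPP, so it is close to the sum of the β-glucan effects and treatment itself can give its calls. The split with 439 calls kept the arms of day 7, so the day 7 effect stayed in it.

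The first pattern weighed was lower haemoglobin and B cell transcripts with higher neutrophil transcripts in HSC of β-glucan mice at day 7. A lower share of stem cells with an unchanged mix of other cells would move the erythroid and neutrophil lists the same way. Their medians differed by 1.82 instead (mean quartile range 0.396). A lower share together with a changed mix could also move the lists apart, so it was not excluded. LT-HSC markers held a mean of 0.285% of counts in each arm. In β-glucan libraries 1 to 3 their share was 0.3342, 0.2481 and 0.2729%, where neutrophil markers held 8.177, 11.82 and 9.745%. Counts freed by the fall of haemoglobin could raise all other genes by a log2 of only 0.056, against a neutrophil median of 0.75 with haemoglobin genes removed. Of the 32 abundant members of the 2 lists, 100% had fold changes in the direction of the pattern, as a changed amount of RNA from red cell precursors and neutrophils among the sorted cells predicts, but these are the lists in which the pattern was seen. Whether the RNA came from contaminating cells or from transcripts within the sorted cells was not tested and stays open.

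The second pattern was the β-glucan effect in HSC at day 28, which called 6 genes with all libraries and 669 without PBS library 2 and β-glucan library 3 (the next of 16 such pairs called 9, the lowest 0). On a scale from the other PBS libraries (0) to the other β-glucan libraries (1), PBS library 2 lay at 0.41 and β-glucan library 3 at 0.56, a difference of -0.15, where an exchange of their labels predicts at least 0.5, but the exchanged grouping called 12 genes, more than the real one. Shares of counts in PBS library 2 and β-glucan library 3 kept the order of the labels for granulocyte-monocyte priming genes (2.206 and 2.309%), haemoglobin (17.1 and 16.69%) and neutrophil markers (7.965 and 7.202%) but had the order of an exchange for LT-HSC markers (0.07802 and 0.08809%) and mitochondrial counts (0.9653 and 1.463%), so an exchange stays open, by a criterion widened to count the 12 calls after both values were known (by the position alone it was excluded). The LT-HSC share of β-glucan library 3 lay among the other β-glucan libraries (0.08177 to 0.08811%), not among the other PBS libraries (0.1031 to 0.1234%). That of PBS library 2 lay below all of them. A GC offset per library called 9 genes with all 8 libraries, so different GC trends are an unlikely source. The pair was chosen from 16 for its count, the scale was defined by the 6 other libraries, so that libraries left out of it tend to lie in the middle, and no biological explanation was tested.

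The third pattern was the set of 431 genes called higher in MPP of β-glucan mice, highest in libraries 3 and 4. In HSC of β-glucan mice the same genes were higher in libraries 3 and 4 than in 1 and 2 by a median of 0.18 (highest of 1000 random lists 0.04), which is consistent with a source shared by those libraries in both cell types, but other groups also lay outside the random range (-0.15 in PBS HSC at day 7). With a GC offset per library 390 genes were called higher, 381 of them among the 431, and 16.2% of these genes had over 20% of their sequence in another gene, against 14.7% of all tested genes, so neither GC trends nor shared sequence is a likely source. Same mouse and shared handling cannot be told apart here, and both stay open.

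The remaining flags mark 1 library far from the other 3 of its group: 22 flags among 285 groups tested (42 of library measures, 243 of gene levels), where chance alone flags about 1 in 20. Among library measures, total counts stood at 35.9 M (35860568) in β-glucan HSC library 2 of day 28 and at 25.1 M (25123374) in PBS HSC library 1 of day 7. Mitochondrial counts were 1.46% in β-glucan HSC library 3 of day 28, B cell markers 0.267% in PBS HSC library 2 of day 28, and haemoglobin 6.81% in PBS HSC library 3 of day 7. In PBS HSC of day 7, library 3 held 10700 CPM of Hba-a2, 17600 CPM of Hba-a1 and 512 CPM of Cd34, and library 4 held 50.7 CPM of Ighv1-82. In PBS HSC of day 28, Prelp stood at 2 CPM in library 4, and Clec7a at 52.6 CPM and Cavin2 at 15.2 CPM in library 2. In MPP of β-glucan mice, library 2 held 10.1 CPM of Lipg and 28.7 CPM of Ighv5-9-1. In MPP of PBS mice, library 3 held 5.64 CPM of Igkv3-12 and 5.23 CPM of Cox5a, and library 4 held 51.1 CPM of Igkv4-91, 0.935 CPM of Slamf1 and 96.1 CPM of Ighv11-2. After 5-FU, Tsc22d3 stood at 353 CPM in β-glucan library 2, and Alox15 at 31 CPM in β-glucan library 1 and at 7.89 CPM in PBS library 2.

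Other flags mark β-glucan effects that differed between groups by a test of the difference (edgeR quasi-likelihood with Benjamini-Hochberg adjustment for genes, camera with an estimated correlation for lists). Day 28 minus day 7 in HSC, the log2 differences were 1.94 for Sptb, 1.98 for Ighd, 5.82 for Igkv4-91, 1.34 for Hba-a2, 1.04 for Epb41 and 1.3 for Ranbp10, and the list medians were -0.42 for cholesterol synthesis and 1.03 for B cell markers. MPP minus HSC, Igkv4-91 differed by -6.64. After 5-FU minus day 28, the differences were -5.89 for Ighv1-49, 1.44 for Il2rb, 1.36 for Alox15, -7.79 for Igkv4-91, -2.19 for Gm23849 and 0.96 for Trac, and the median of T and NK cell markers was 0.68.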

How the results depend on the processing

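The alternatives that leave out 2 or more libraries together, the GC offset, the surrogate factor and the removal of haemoglobin genes were chosen after the results had been seen. For genes named in the text, 6909 values under all alternatives stayed on their side of the threshold, 612 lost and 401 gained a call, and 1 called value changed sign. For single gene lists, 1567 stayed, 310 lost their call and 2 changed direction. Of the counts of calls and the tests of day 7 genes, 194 stayed (counts within 1.5 times), 119 counts moved further, and 4 tests lost and 1 gained a call. All 124 library shares stayed within 1 SD of the group. That outcome was fixed in advance, since leaving out 1 of 3 or 4 libraries cannot move a mean that far. DESeq2 size factors moved no count by over 1.5 times. In the simulated data a larger share of calls was false with the DESeq2 test than with edgeR in all 8 comparisons, such as 43 of 232 against 17 of 198 after 5-FU. Where no cause is named below, the cause was not tested. Groups of 3 or 4 limit what single genes can show, most of all for changes below 2-fold.

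In HSC at day 7 (1102 genes called), the counts were 1711 with DESeq2, 1744 with limma voom, 1971 with all 8 groups in 1 fit and 85 for a fold over 1.5. Leaving out 1 library gave 500 (β-glucan library 3) to 1252, with 559 without β-glucan library 2 and 643 without PBS library 2. For HSC at day 28 (6), they were 182 without a filter, 589 with DESeq2, 598 with limma voom, 525 with all 8 groups, 2 for a fold over 1.5, 69 with a surrogate factor, 3 without β-glucan libraries 3 and 4 and 669 without PBS library 2 and β-glucan library 3. Single libraries left out gave 1 to 51, with 51 without PBS library 2, 28 without β-glucan library 3, 1 without PBS library 3 or 4, 2 without PBS library 1, and 3 without β-glucan library 1, 2 or 4. In MPP (733), they were 1181 without a filter, 1301 with DESeq2, 228 with all 8 groups, 0 for a fold over 1.5 by edgeR's glmTreat (3059 genes with p under 0.05 in the test without a fold, limma voom 640), 189 without β-glucan libraries 3 and 4, and 12 with a surrogate factor, which itself separated the arms. With any 1 library left out it was 164 to 1010: 257, 164, 197 and 319 without PBS libraries 1 to 4 in turn, and 266 and 337 without β-glucan libraries 3 and 4. After 5-FU (7), they were 110 without a filter, 16 with a stricter filter, 147 with DESeq2, 42 with limma voom, 94 with all 8 groups, 1 for a fold over 1.5 and 23 with a surrogate factor. Without 1 library the range was 2 to 61, with 61 without PBS library 3, 14 without β-glucan library 4, 4 without PBS library 1 or β-glucan library 3, and 2 without PBS library 2 or β-glucan library 1 or 2. Between MPP and HSC (3493), they were 273 for a fold over 1.5, 5361 with a surrogate factor and 2004 (without MPP library 1) to 5050 with 1 library left out.

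For the difference between day 28 and day 7 (866), the counts were 1432 with DESeq2, 1611 with limma voom, 1461 with all 8 groups and 551 without β-glucan libraries 3 and 4 of day 28. With 1 library left out the range was 445 to 1051, with 445 and 520 without β-glucan libraries 2 and 3 of day 7 and 537 without β-glucan library 1 of day 28. For MPP against HSC (1), they were 2 without a filter, with DESeq2 and with all 8 groups, 4 without libraries 3 and 4 of β-glucan HSC, and 0 by edgeR without libraries 3 and 4 of β-glucan MPP (826 genes with p under 0.05) or of both (1017), where with all libraries limma voom called 1. Each library left out in turn gave 1 to 3: 3 without PBS HSC library 3, and 2 without PBS HSC library 2, β-glucan HSC library 3 or β-glucan MPP library 1. For 5-FU against day 28 (18), they were 59 without a filter, 151 with DESeq2, 118 with limma voom, 41 with all 8 groups and 2 without β-glucan libraries 3 and 4 of day 28. Leaving out 1 library gave 6 to 49, with 49 without β-glucan library 3 and 38 without PBS library 2 of day 28, and 6 to 11 without any of 11 others.

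The replicate block, which pairs libraries by number, changed the count to 645 in HSC at day 7, 14 in HSC at day 28, 16 after 5-FU, 2 for MPP against HSC and 7 for 5-FU against day 28; the others stayed within 1.5 times. Same-numbered libraries deviated together with correlations of -0.189 to 0.0654 at day 7, -0.0875 to 0.347 in HSC at day 28, -0.11 to 0.334 in MPP, -0.133 to -0.047 after 5-FU and 0.0818 to 0.328 between MPP and HSC of PBS mice. Between MPP and HSC of β-glucan mice they were 0.244 to 0.489, over 0.1 for all 4 numbers, with 5 of 8 libraries correlating best with their own number (6 of 8 in PBS mice). The numbers were not taken as pairs in the main fits, because the labels do not say what they mark. In each fitted comparison of 2 groups at least 1 number stayed under 0.1 (0.0818 between MPP and HSC of PBS mice), which does not exclude a shared source. MPP against HSC and the difference between their β-glucan effects were fitted as independent libraries, so their p-values do not allow for such a source. MPP and HSC of β-glucan mice alone were not compared in a fit.

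Of the gene lists called by camera (21, 14, 12 and 11 in the 4 β-glucan comparisons, 16 between cell types and 16, 6 and 19 for the differences), an estimated correlation left 1, 1, 3, 0, 0, 2, 0 and 1. With 0 lists left after 5-FU, fry called 2 by direction and 7 in either direction; with 0 between cell types, fry called 33 in either direction; with 0 for MPP against HSC, fry called 1 by direction and 2 in either direction. By direction, fry called 13 at day 7, 6 in HSC at day 28 and 4 for 5-FU against day 28, and in either direction 22 in HSC at day 28, 29 in MPP and 25 for day 28 against day 7. Leaving out 1 library gave 7 (without β-glucan library 1) to 15 lists after 5-FU. For MPP against HSC it gave 2 (without β-glucan MPP library 4) to 15 (without PBS HSC library 2), with 3 without PBS HSC library 1 or 3, β-glucan HSC library 4 or PBS MPP library 3, and 3 without libraries 3 and 4 of β-glucan HSC. The ribosomal protein list in MPP turned up without β-glucan libraries 3 and 4 (camera adjusted p = 0.0232) and without library 3 alone (0.783; 1.06e-05 to 0.783 over single libraries). Flt3 in MPP turned to -0.09 with a surrogate factor. With lists of 200, the genes lower at day 7 were called in HSC at day 28 (camera adjusted p = 0.00834, and 0.978 with an estimated correlation). The genes higher at day 7 lost their call in MPP (camera adjusted p = 0.1). For the full lists with an estimated correlation, camera gave adjusted p = 0.927 for the higher genes and 0.63 for the lower genes in MPP, and 0.63 for the lower genes after 5-FU.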

Other observations

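The gene groupings in this part were picked after the results had been seen, and no further test was run on them. The granulocyte-monocyte priming list was not called in MPP at day 28 (median 0.03, camera adjusted p = 0.363), and single granulocyte genes went both ways. The primary granule genes Elane (0.25 ± 0.06), Ctsg (0.27 ± 0.06) and Prtn3 (0.43 ± 0.06), with Ms4a3 (0.36 ± 0.05) and the granulocyte factor Cebpe (0.27 ± 0.06), rose, while the later granule genes Ltf (-0.41 ± 0.08), Camp (-0.43 ± 0.09), Ngp (-0.41 ± 0.10) and Chil3 (-0.33 ± 0.08) fell. At day 7 in HSC all of these rose, by 0.99 ± 0.13 for Elane, 0.90 ± 0.13 for Cebpe, 0.73 ± 0.13 for Ltf and 0.81 ± 0.13 for Ngp. In HSC at day 28 none was called, with Elane at 0.50 ± 0.12, Cebpe at 0.48 ± 0.11, Ltf at -0.34 ± 0.12 and Ngp at -0.25 ± 0.12. Across all genes, 140 were called both at day 7 in HSC and at day 28 in MPP: 28 higher in both, 59 lower in both, 45 higher then lower and 8 lower then higher.

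Protein folding genes of the endoplasmic reticulum were called in both HSC and MPP: Hspa5 rose at day 7 (0.29 ± 0.08) and in MPP (0.38 ± 0.05), and so did Manf (0.35 ± 0.08 and 0.43 ± 0.04). Lipg, endothelial lipase, rose in HSC at day 7 (2.42 ± 0.35), in HSC at day 28 (1.38 ± 0.19) and in MPP (1.26 ± 0.15), and stood at -0.26 ± 0.18 after 5-FU without a call. In HSC at day 28 without PBS library 2 and β-glucan library 3, the pair of 16 picked for its count, 669 genes were called, among them Txnip (-0.92 ± 0.09), Prtn3 (0.64 ± 0.06), Elane (0.65 ± 0.07) and the B cell gene Ms4a1 (-0.62 ± 0.08). With those libraries left out, 5 LT-HSC markers, 8 type I interferon and 8 interferon gamma genes fell, and 5 unfolded protein response, 4 DNA replication and 5 mitosis genes rose. Markers of other cells were called in the same fit: 4 T and NK cell and 3 neutrophil markers fell, 3 B cell markers fell and 1 rose, and 5 mast cell and eosinophil and 2 stromal markers rose. Of 13 genes of the mitochondrial genome, 3 fell.

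Ribosomal protein genes aside, genes that share sequence with other genes stood lower in the day 7 table, by a comparison across tables chosen after the data were seen and not tested. Among genes of mean log2 CPM over 2, ribosomal protein genes aside, those with over 60% of their sequence in another gene differed between PBS HSC of day 7 and of day 28 by a median log2 of -1.81 (488 genes) and those with 20 to 60% by -0.77 (752 genes), against -0.05 for genes with none (5999 genes). Between PBS HSC after 5-FU and at day 28 the first value was 0.05, and between β-glucan and PBS HSC at day 7 it was 0.04. By their medians, ribosomal protein genes were not lower in PBS HSC of day 7 than of day 28. Their median difference was 0.31 with over 60% shared (6 genes) and 0.32 with 20 to 60% (45 genes). The lower quartiles were -0.28 and -0.78, so part of these genes stood lower too.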
